A study of Mus musculus with 6 samples.

How the data were processed

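RNA was measured in 6 samples of HEI-OC1, 3 of the control line and 3 labelled Nrf2 KO, each sequenced as a poly(A)-selected library. Per the submitters' processing notes, the tools were fastp, FastQC, HISAT2 and DESeq2 1.34.0, with no role or order given, and the build was the human hg18. The counting tool, its strand setting and the annotation are not given in the sources used here. The deposited counts were whole numbers per gene symbol for each library, with totals that differ as in unnormalised counts. The authors' second deposited table gives FPKM as 1 value per group, with no value per library, and how the FPKM were made is not given in the sources used here.

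The gene symbols of both tables follow rat nomenclature, although the labels give mouse cells and the notes a human build. Of 30438 symbols, 650 began with RGD, 40 with RT1 and 1202 with Olr, names used for rat genes, 10844 began with LOC, and 0 carried the mouse prefixes H2- or Gm. No mitochondrially encoded gene was listed, and 9586 symbols had 0 counts in all 6 libraries. Symbols that are also current mouse symbols numbered 16256 and held 91.9% of the counts. Whether the reads were aligned to the rat genome is not given in the sources used here. Mouse reads counted on rat gene models would be lost unevenly between genes, which would affect levels set between genes more than the ratio of 1 gene between groups. Without a stated strand setting, reads of overlapping and antisense genes cannot be separated. Columns of other samples numbered 0.

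Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group (minimum count 10, minimum total count 15), which left 14618 genes. Libraries were scaled by TMM, and the quasi-likelihood model with robust estimation held the group as its only term. The two-sided p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. All adjusted p-values of genes come from this test unless another tool is named. Levels are CPM with TMM scaling, given as mean ± SD of 3 libraries, and fold changes carry the standard error of the fitted model. The log2 CPM used for principal components, correlations and list tests had a prior count of 2.

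Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, two-sided and adjusted over the lists, and again with an estimated correlation and with fry. Of 44 lists, 42 had at least 5 tested members, and the mitochondrially encoded and leukocyte lists did not. The lists, the tests and the rule for naming genes were set before the data were examined. Of 1231 list symbols 1170 were in the table, 22 of them under an older name of the gene. The use of older names was added after the results with exact symbols had been seen. Camera called 15 lists with a preset correlation, 9 higher and 6 lower, and 0 with an estimated correlation. By fry, which does not compare a list with other genes, 13 lists moved on balance in 1 direction and 36 held changes in either direction. Camera did not call these lists that fry passed in 1 direction: platinum transport (adjusted p = 0.0336), p53 (0.0130) and hair cell (0.0105). The same held for neuron and glia (0.0336) and melanocyte markers (0.0370). Of the camera calls, fry did not pass the NRF2 target (0.208), ribosomal (0.0808), oxidative phosphorylation (0.0808) or S phase (0.106) lists. Nor did fry pass the G2 and M (0.208), cholesterol (0.125) or protease (0.0573) lists.

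The genes named were Nfe2l2 and Keap1, and the 10 largest and 10 smallest log2 fold changes among called genes with a mean CPM of at least 5 and no overlap between the groups, leaving out unnamed genes. In each list up to 4 called members with the smallest p were named, or the 2 members with the highest CPM where none was called. A list member with 0 counts in 1 group and at least 50 counts in each library of the other would also have been named. Nqo1, Gclc, Aldh3a1, Hmox1, Col1a1, Col6a3, Gstt1, Gstt2, Gstt3, Gsto1, Epha2, Ephb3, Adamts12, Itga6 and Cacnb2 lie outside this rule and were chosen after their values were seen, as were the genes at the ends of gene-order stretches. Some genes that the rule takes are not reported here.

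The libraries were compared for duplicates by a chi-square of their counts over genes. The smallest chi-square per degree of freedom within a group was 12.2, between replicates 2 and 3 labelled Nrf2 KO, so no pair differed by as little as sampling noise. The labels number the replicates but do not say what a number marks. Each library's deviation from its group mean was therefore correlated across genes with that of the library of the same number in the other group. The correlations were 0.754, 0.696 and 0.310 for numbers 1, 2 and 3, all above the 0.1 set as the limit, so the numbers were taken as pairs, on the evidence of the counts and not of the labels. Nrf2 KO replicate 3 correlated more with control replicate 2 (0.539) than with control replicate 3. The unmatched control replicate 3 and Nrf2 KO replicate 2 also passed the limit (0.278). Deviations cancel out within a group, so a shared deviation of replicate 1 alone can give such values. The counts therefore cannot settle how replicates 2 and 3 pair. The fit with the replicate number as a block is given beside a result where it changed the call or moved a count by more than 1.5 times.

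The edgeR test was tested on simulated data for the comparison of the libraries labelled Nrf2 KO with control, over 14422 genes with the dispersions of these libraries. It recovered 4 of 99 genes changed 2-fold (4.04%) and 62 of 93 changed 4-fold (66.7%), with 5 false calls among 71. The simulation holds no pairing, so these shares are for the fit without the block. With the block 2678 genes were called, of which 784 were higher and 558 lower at least 2-fold. In a simulated comparison camera called a list of 30 genes raised 2-fold and did not call a list of 30 unchanged genes. The simulated genes were drawn independently of each other, so this does not test false list calls among correlated genes.

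The alternatives were scaling by median-of-ratios, upper quartile or library size, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, a threshold of 0.01, the replicate block, a test against a log2 fold change of 1, and each library left out in turn. Alternatives chosen after seeing the data were the fits without both replicate 1 libraries and with exact list symbols. The planned limma tests on FPKM could not be run because the FPKM table holds no value per library. In their place the log2 ratio of the group FPKM, with a pseudocount of 0.1, was compared with the log2 fold change of the counts across the 14618 genes. Pearson's r across genes, which are not independent replicates, was 0.915, and all 1211 called genes had the same direction. Both tables describe the same 2 groups of libraries, so the shared direction is no independent check of the calls.

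For tests along the gene order and of transcript GC content, symbols were matched to a table of mouse genes of the assembly GRCm38.p6, which placed 11169 of the tested genes in order. Transcript length was taken from the ratio of count to FPKM in the deposited tables, which gave a value for 100% of the tested genes. Over genes matched by symbol, this implied length had a Spearman correlation of only 0.414 with mouse transcript length. GC content was found for 77.1% of them.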

Results

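Gene expression was measured by poly(A)-selected RNA sequencing in HEI-OC1, a conditionally immortalised cell line derived from the mouse organ of Corti that serves as a model of hair cell toxicity. The labels describe it as a cochlear stem cell. Libraries came from 2 groups of 3: unedited HEI-OC1 as the control, and HEI-OC1 labelled as knocked out for Nrf2. Nrf2 is the transcription factor encoded by Nfe2l2 that drives antioxidant and detoxification genes. All cells were grown at 33 °C in 10% CO2 with 10% serum, and no drug treatment is recorded in the labels. The question given by the submitters is which genes could account for the greater cisplatin resistance of the knockout cells, so the 1 comparison of the design is knockout against control in untreated culture. The control libraries held 38636523, 44098578 and 38945498 counts and the libraries labelled Nrf2 KO held 29130007, 51285343 and 43246180, for replicates 1, 2 and 3.

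The first principal component separated the groups and carried 51.2% of the variance, and the second carried 41.2% and set replicate 1 of both groups apart from the rest. Pearson's r of log2 CPM, counts scaled to the library's total, across genes lay between 0.978 and 0.993 within the control group. It was 0.995 between replicates 2 and 3 labelled Nrf2 KO, and 0.931 and 0.939 between replicate 1 and those libraries. Replicates 2 and 3 labelled Nrf2 KO were closer to control replicates 2 (0.959 each) and 3 (0.952 and 0.956) than to their own replicate 1. Nrf2 KO replicate 1 had an r of 0.938, 0.907 and 0.919 with control replicates 1, 2 and 3. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

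**Figure D1:**
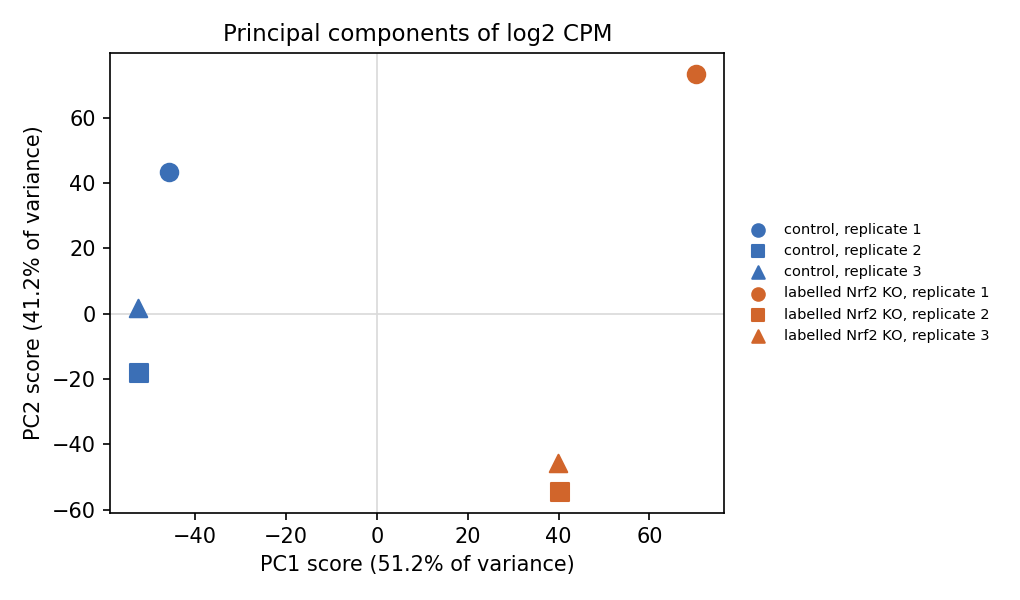
Scores of the 6 libraries on the first and second principal components of log2 CPM, in arbitrary units, with colour for the group and marker shape for the replicate number. On the second component, replicate 1 scored 43.4 in the control group and 73.4 in the group labelled Nrf2 KO, and no other library scored above 1.70.

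Nfe2l2 itself was higher, not lower, in the libraries labelled Nrf2 KO. Its level was 74.2, 126.5 and 96.7 CPM in the control libraries and 395.7, 235.6 and 204.5 CPM in the libraries labelled Nrf2 KO, a mean of 99.1 ± 26.2 against 278.6 ± 102.6 (SD, n = 3 each). The log2 fold change was 1.49 (SE 0.33, adjusted p = 0.0456 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The authors' deposited table, which describes the same groups and is no independent check, gives Nfe2l2 a group FPKM of 94.9 for the group labelled Nrf2 KO and 33.8 for the control. The transcript level therefore goes against the label, and every direction given here is that of the libraries labelled Nrf2 KO over control. A gene-level count checks nothing about an edit that leaves the transcript in place, and the position of the edit is not given in the sources used here. The call for Nfe2l2 was close to its threshold: it was lost with upper-quartile scaling (adjusted p = 0.0526), with library size alone (0.0593), and without control replicate 1 (0.167), 2 (0.102) or 3 (0.202) or Nrf2 KO replicate 2 (0.102) or 3 (0.0784).

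Of 40 tested NRF2 target genes, 3 were lower and 0 higher in the libraries labelled Nrf2 KO, and the counts adjusted over the list alone were also 3 and 0. At an unadjusted p under 0.05 edgeR gave 10 lower and 0 higher, DESeq2 called 7 lower and 0 higher, and limma-voom 4 and 0. Ephx1, an epoxide hydrolase, went from 1.55 ± 0.147 to 0.0677 ± 0.0619 CPM (log2 fold change -4.37, SE 0.65). Gstp1, a glutathione transferase, had a log2 fold change of -1.43 (SE 0.26). Reads of Gstp1 can be split with near-identical copies, so its level is uncertain. With the replicate number as a block, 6 targets were lower and 0 higher. The added genes were Nqo1 (log2 fold change -1.31, SE 0.55, adjusted p = 0.204 unblocked and 0.0315 blocked), Gclc (-0.66, SE 0.16, 0.0576 and 0.0352) and Aldh3a1 (-1.03, SE 0.26, 0.0685 and 0.0300), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These 3 genes and Hmox1 (-0.26, SE 0.13, adjusted p = 0.268) were singled out after their values were seen.

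As a set, the NRF2 targets had a median log2 fold change of -0.14 and were called lower by camera with a preset correlation (adjusted p = 0.0495). Of 17 alternatives, 8 kept the call, with adjusted p from 0.00986 to 0.0496: the 3 other scalings, limma-voom, no filter on low counts, and the fits without control replicate 1 or Nrf2 KO replicate 2 or 3. It was lost with a filter of 1 CPM (0.0632), with an estimated correlation (adjusted p = 0.646), with the replicate block (0.0883), and when list symbols were matched exactly without older gene names (0.0883). The matching of older names was added after the exact-symbol result had been seen, so the call rests on that choice. It was also lost without control replicate 2 (0.0632) or 3 (0.0643), and without Nrf2 KO replicate 1 the median turned to 0.07 (0.845), with 4 targets higher and 8 lower. Without both replicate 1 libraries, 10 targets were higher and 12 lower.

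Among 13 tested regulators of the pathway, a list that holds Nfe2l2 itself, 2 were higher (Nfe2l2 and Maff) and 1 lower. Adjusted over the list alone 3 were higher and 1 lower, and with the replicate block, as without Nrf2 KO replicate 1, 4 and 1. Mafk, a small MAF protein that partners NRF2 on DNA, fell from 77.7 ± 2.89 to 35.1 ± 1.91 CPM (log2 fold change -1.15, SE 0.13), and Maff, another small MAF protein, was higher (0.92, SE 0.18). Keap1, the adaptor that targets NRF2 for degradation, was at 35.2 ± 2.84 and 38.6 ± 5.71 CPM, with an adjusted p of 0.687.

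**Figure D2:**
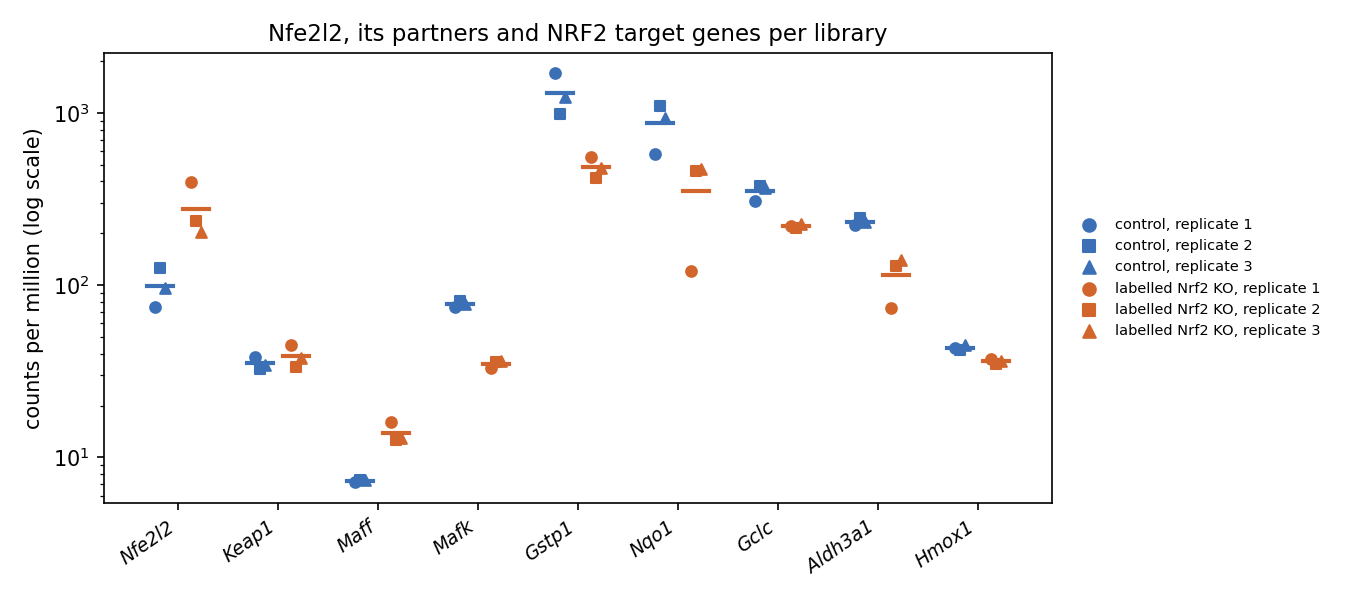
CPM on a log axis of Nfe2l2, pathway regulators and NRF2 targets, with 1 point per library, marker shape for the replicate number and a bar at each group mean. Ephx1 is left out because 1 library had 0 counts. All 3 Nfe2l2 points labelled Nrf2 KO (204.5 to 395.7 CPM) lie above the control points (74.2 to 126.5), while Mafk and Gstp1 lie below theirs.

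Across 14618 tested genes, 706 were higher and 505 lower in the libraries labelled Nrf2 KO (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), of which 521 and 360 changed at least 2-fold. The largest increases were in genes that were nearly silent in the control libraries. Sema5a, a semaphorin, had 2, 2 and 0 counts in the control libraries and 335, 1054 and 743 in those labelled Nrf2 KO. Fhod3, an actin-assembling formin, had 3, 1 and 0 against 404, 936 and 723. The others of the top 10 were Postn (periostin, a matrix protein), Robo1 (a Slit receptor), Tpd52, Slc8a1 (a sodium-calcium exchanger), Angpt4, Cacna2d1 (a calcium channel subunit), Pcdh17 and Ncam1, the neural cell adhesion molecule, which rose from 1.08 ± 0.184 to 97.8 ± 28.8 CPM.

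Among the 10 largest decreases, Fabp5, a fatty acid binding protein, fell from 32.7 ± 7.38 to 1.14 ± 0.213 CPM (log2 fold change -4.83, SE 0.28), and Plin2, a lipid droplet coat protein, from 16.3 ± 2.89 to 1.27 ± 0.441 CPM (-3.67, SE 0.34). Atox1, a copper chaperone, fell from 18.6 ± 5.06 to 1.00 ± 0.206 CPM (-4.20, SE 0.31). Ott, Ptprz1 (a receptor tyrosine phosphatase), Clec3b, Igfbp5, Tmem176b, Tmem176a and Wwc1 made up the rest, with log2 fold changes between -5.66 and -3.76. Of these 20 genes, Igfbp5 and Slc8a1 lost the call in at least 1 fit with a library left out, and the other 18 passed in all 6 such fits.

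The number of calls moved strongly with the libraries used. With the replicate block 1520 genes were higher and 1158 lower. Without Nrf2 KO replicate 1 the counts were 2323 and 2162, and without both replicate 1 libraries, a choice made after the principal components were seen, 3540 and 3253. Each of these fits kept all 1211 calls. Leaving out control replicate 1 gave 208 and 103, control replicate 2 gave 203 and 98, control replicate 3 gave 139 and 57, Nrf2 KO replicate 2 gave 266 and 110, and Nrf2 KO replicate 3 gave 271 and 110. Of 125 called genes named here, 39 passed in all 6 fits with a library left out, among them Col1a2, Thy1, Pdgfra, Tnc, Fbn1, Col18a1, Adamts9, Itga9, Itga8, Ncam1, Myo7a, Fst, Fas, Abcb1b, Gbp2, Cyr61, Ctgf and Dusp6. The other 86 lost the call without at least 1 library other than Nrf2 KO replicate 1 and kept their direction. Counts within the gene lists, over the members tested in each fit, moved in the same way. Summed over the lists, with a gene of 2 lists counted in each, 95 members were higher and 52 lower with all 6 libraries, 263 and 164 without Nrf2 KO replicate 1, and 349 and 242 without both replicate 1 libraries. Without any 1 of the other 5 libraries the sums were between 20 and 45 higher and between 6 and 14 lower. In those 5 fits only the matrix, fibroblast, adhesion, protease, supporting cell and immediate early lists held more than 2 called members in 1 direction.

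Among extracellular matrix and mesenchymal genes, more passed higher than lower in the libraries labelled Nrf2 KO, and with all 6 libraries most of each list did not pass. Of 36 tested matrix and basement membrane genes, 13 were higher and 3 lower (18 and 4 adjusted over the list alone, 23 and 4 without Nrf2 KO replicate 1, and 2 to 7 and 1 to 3 without 1 of the other libraries), with a median log2 fold change of 0.86. Tnc, the matrix glycoprotein tenascin-C, rose from 9.94 ± 0.617 to 65.7 ± 5.37 CPM (log2 fold change 2.72, SE 0.15), and Fbn1, the microfibril protein fibrillin-1, to 58.7 ± 14.2 CPM (2.42, SE 0.23). The lower members included Col18a1 (-2.57, SE 0.28) and Loxl1, a lysyl oxidase (-1.76, SE 0.20). Of 20 fibroblast and otic mesenchyme markers, 8 were higher and 1 lower (9 and 2 adjusted over the list alone, 12 and 2 of the 21 tested without Nrf2 KO replicate 1, and 4 to 5 and 0 of 20 or 21 tested without 1 of the other libraries), with a median of 1.04. Col1a2, a type I collagen chain, rose from 172 ± 26.2 to 1656 ± 367 CPM (3.27, SE 0.27), and the growth factor receptor Pdgfra from 53.5 ± 5.78 to 205 ± 31.2 CPM (1.94, SE 0.18). Thy1, a surface glycoprotein, had a log2 fold change of 1.88 (SE 0.17).

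Of 27 integrin and adhesion genes, 7 were higher and 1 lower (13 and 2 adjusted over the list alone, 14 and 1 with the replicate block, 20 and 1 without Nrf2 KO replicate 1, 3 to 6 and 0 without 1 of the other libraries), with a median of 0.84 and 25 positive values. Besides Ncam1, these included Itga9 (log2 fold change 4.02, SE 0.32), Itga8 (4.09, SE 0.42) and Zyx, a focal adhesion protein (1.37, SE 0.17). Of 22 matrix proteases and inhibitors, 5 were higher and 2 lower (9 and 2 adjusted over the list alone, 8 and 2 with the replicate block, 11 and 2 without Nrf2 KO replicate 1, 1 to 3 and 0 to 2 without 1 of the other libraries). Adamts9 had 0, 0 and 2 counts in the control libraries and 176, 334 and 226 in those labelled Nrf2 KO, while Mmp11 was lower (-1.64, SE 0.21). Camera called the matrix (adjusted p = 0.000172), fibroblast (8.54e-05), adhesion (4.47e-06) and protease (0.0355) lists higher. With an estimated correlation each of these had an adjusted p of 0.560. The protease call was lost without control replicate 2 (0.0508) or Nrf2 KO replicate 2 (0.0612) or 3 (0.0660), and the other 3 were kept in every fit with a library left out.

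**Figure D3:**
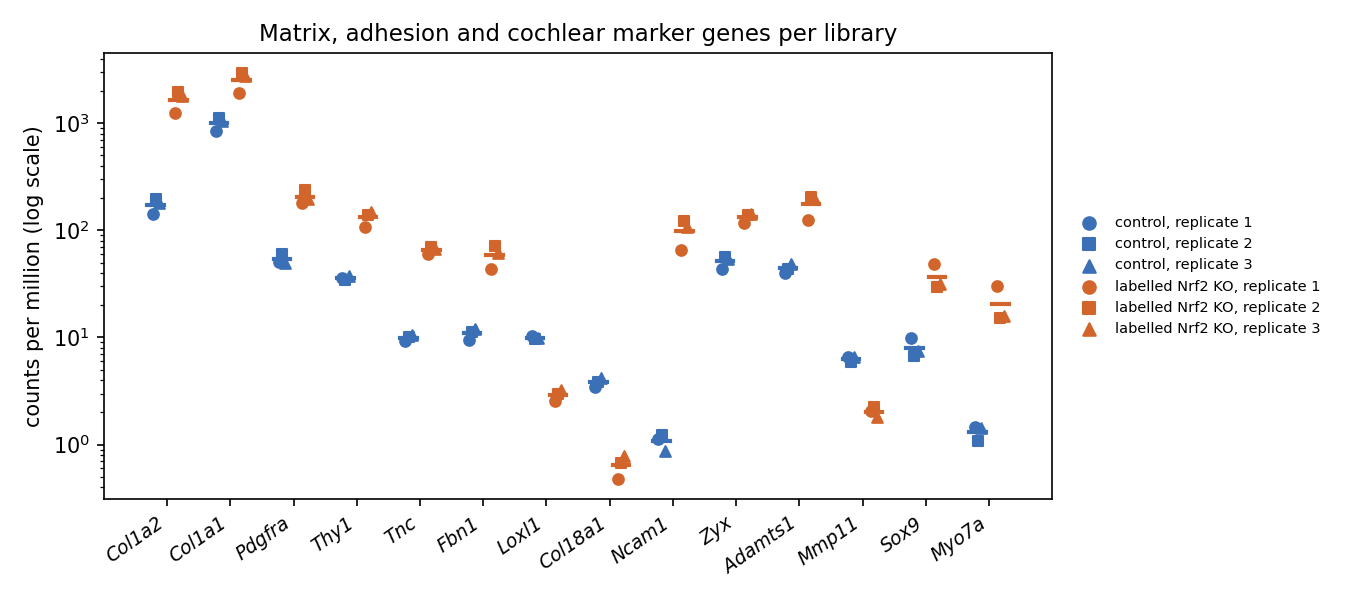
CPM on a log axis of matrix, adhesion, protease and cochlear marker genes, with 1 point per library, marker shape for the replicate number and a bar at each group mean. The groups did not overlap in any plotted gene: Col1a2, Tnc, Ncam1 and Sox9 lay higher in the libraries labelled Nrf2 KO, and Loxl1, Col18a1 and Mmp11 lay lower.

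Some markers of cochlear cell types were also higher. Of 34 supporting cell and prosensory markers, 19 had enough counts to test. Of these 19, 5 were higher and 0 lower, and the same counts held adjusted over the list alone. At an unadjusted p under 0.05 edgeR gave 8 and 0, DESeq2 called 7 and 0, and limma-voom 5 and 0, and edgeR without Nrf2 KO replicate 1 gave 7 and 1. Fst, which encodes follistatin, rose from 24.6 ± 1.91 to 109 ± 14.3 CPM (log2 fold change 2.15, SE 0.16), and Sox9, a transcription factor of the early inner ear, from 8.02 ± 1.60 to 36.6 ± 10.6 CPM (2.19, SE 0.27). Lgals3 (1.86, SE 0.20) and Bmp4 were higher as well. Camera called the list higher (adjusted p = 0.0344). The call was lost with an estimated correlation (adjusted p = 0.560), with the replicate block (0.0670) and without Nrf2 KO replicate 1 (0.0900) or both replicate 1 libraries (0.0987).

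Of 32 hair cell markers, 5 had enough counts to test. Of these, Myo7a, an unconventional myosin of hair cells, rose from 1.32 ± 0.207 to 20.3 ± 8.35 CPM (log2 fold change 3.95, SE 0.36). Markers of other cell types gave few calls: 1 of 6 epithelial markers was higher (Krt7), 1 of 7 neuron and glia markers was lower (Gap43; 2 with the replicate block, 3 without Nrf2 KO replicate 1), and 1 of 4 leukocyte markers was lower (Laptm5). Of the 6 melanocyte and stria markers edgeR called 0 (1 higher at an unadjusted p under 0.05), and DESeq2, limma-voom and edgeR with the replicate block each called 1, while 2 were higher and 2 lower without Nrf2 KO replicate 1. The epithelial list passed camera only without Nrf2 KO replicate 2 (adjusted p = 0.0435) among the fits run. Of 8 endothelial and pericyte markers, 1 was higher (Erg, at 0.852 ± 0.424 CPM) and 2 were lower (Mcam and Des; 4 with the replicate block or without Nrf2 KO replicate 1), with a median of -1.20. Camera called that list lower (adjusted p = 0.0334, and adjusted p = 0.560 with an estimated correlation), a call lost without control replicate 2 (0.0508), Nrf2 KO replicate 1 (0.156) or both replicate 1 libraries (0.0987), and with no filter on low counts (0.0709).

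Members of the list drawn up for platinum transport, which also holds general drug efflux pumps, changed in both directions. Uptake or efflux of cisplatin was not measured. Of 19 tested genes of platinum transport and metallothioneins, 4 were higher and 1 lower (7 and 3 adjusted over the list alone, 6 and 3 with the replicate block, 9 and 3 without Nrf2 KO replicate 1). Abcb1b, a multidrug efflux pump, rose from 0.671 ± 0.150 to 4.65 ± 0.368 CPM (log2 fold change 2.78, SE 0.27), and the metallothionein Mt1 from 1.42 ± 0.584 to 12.4 ± 5.40 CPM (3.12, SE 0.45). The member that fell was Atox1, described above. The list as a whole did not pass camera (adjusted p = 0.0879). Fry, which does not compare a list with other genes, called it higher (adjusted p = 0.0336).

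Of 35 excision and crosslink repair genes, 2 were lower and 0 higher by edgeR (3 and 1 at an unadjusted p under 0.05, 2 and 1 by DESeq2, by limma-voom and by edgeR with the replicate block, 8 and 1 without Nrf2 KO replicate 1): the mismatch repair gene Pms2 (log2 fold change -1.12, SE 0.17) and Fancf (-0.86, SE 0.18). Of 21 antioxidant enzymes outside the NRF2 list, Sod3, the extracellular superoxide dismutase, and Gpx8 were higher (1.54, SE 0.29, and 0.88, SE 0.20), and 1 member was lower with the replicate block, and 7 were higher and 2 lower without Nrf2 KO replicate 1. Among 23 p53 targets, 3 were higher and 1 lower (5 and 1 with the replicate block, 6 and 3 without Nrf2 KO replicate 1), led by Fas, a death receptor, which rose from 0.465 ± 0.174 to 4.91 ± 0.370 CPM (3.39, SE 0.34). Fas was also the 1 call among 24 pro-apoptotic genes, of which 2 were higher and 1 lower with the block and 2 and 3 without Nrf2 KO replicate 1. Of 13 anti-apoptotic genes, Birc2 was higher (0.72, SE 0.15) and Bag1 lower (-0.65, SE 0.13), and 4 were higher and 1 lower with the block. The ferroptosis list had 2 higher members of 25, the iron exporter Slc40a1 (2.09, SE 0.24) and Sat1 (2.37, SE 0.35), 5 with the block, and 8 with 1 lower without Nrf2 KO replicate 1. With all 6 libraries camera called none of the repair, antioxidant, p53, apoptosis or ferroptosis lists. It called the anti-apoptotic list higher without Nrf2 KO replicate 1 (adjusted p = 0.0214, 6 members higher) and without both replicate 1 libraries (0.0285, 9 members higher).

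Of 30 tested interferon-stimulated genes, 10 were higher and 1 lower (12 and 3 adjusted over the list alone, 16 and 3 with the replicate block, 18 and 3 without Nrf2 KO replicate 1), with a median log2 fold change of 0.75. Gbp2, a guanylate binding protein, rose from 2.70 ± 0.103 to 15.4 ± 3.53 CPM (2.51, SE 0.24), and Usp18 (2.04, SE 0.31) and Parp9 (1.17, SE 0.15) were higher, while the immunoproteasome subunit Psmb8 fell (-2.44, SE 0.29). Camera called the list higher (adjusted p = 0.000926, and adjusted p = 0.560 with an estimated correlation). Of 20 genes of NF-kB and inflammation, 2 were higher, Tnfaip3 (1.35, SE 0.17) and Nfkb1 (0.92, SE 0.13), and Vcam1 was lower (-2.81, SE 0.42). Adjusted over the list alone 4 were higher and 2 lower, with the replicate block 6 and 2, and without Nrf2 KO replicate 1 8 and 2. That list passed camera at an adjusted p of 0.0495. The call was lost with an estimated correlation (adjusted p = 0.560), with the block (0.0569), library size alone (0.0536), a filter of 1 CPM (0.0523) or exact list symbols (0.0516), without both replicate 1 libraries (0.0873), and without control replicate 2 (0.0867) or 3 (0.0524) or Nrf2 KO replicate 1 (0.0988) or 3 (0.101).

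Of 32 immediate early genes, 7 were higher and 1 lower (10 and 5 adjusted over the list alone, 11 and 3 with the replicate block, 11 and 5 without Nrf2 KO replicate 1). Cyr61 and Ctgf, matricellular proteins, had log2 fold changes of 2.33 (SE 0.22) and 2.10 (SE 0.20), and Dusp6, a phosphatase of ERK, one of 2.39 (SE 0.27). Atf3, a stress-induced transcription factor, was lower (-2.51, SE 0.34). The list did not pass camera (adjusted p = 0.0511), but did with upper-quartile scaling (0.0493) and without control replicate 1 (0.0375) or 3 (0.0421) or Nrf2 KO replicate 2 (0.0255). With exact list symbols, which leave out Cyr61 and Ctgf as older names, 30 members were tested and the adjusted p was 0.209. These values near the threshold therefore rest on the older names, which were added after the exact-symbol results had been seen. Of 22 integrated stress response genes, 3 were lower and 0 higher (8 and 1 adjusted over the list alone; 10 and 2 by edgeR at an unadjusted p under 0.05, 8 and 2 by DESeq2, 5 and 0 by limma-voom, 9 and 1 with the replicate block, 10 and 3 without Nrf2 KO replicate 1): Atf3, the amino acid transporter Slc7a1 (-1.22, SE 0.17) and Cebpg (-0.67, SE 0.13). Camera called that list lower at an adjusted p of 0.0495, and no fit with a library left out kept the call (0.0784 to 0.168), nor did the block (0.0883), upper-quartile scaling (0.05003), no filter on low counts (0.0848), exact list symbols (0.0530), the fit without both replicate 1 libraries (0.0987) or an estimated correlation (adjusted p = 0.560).

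The ribosomal protein and oxidative phosphorylation lists had negative medians. With all 6 libraries few members passed alone, and more did without Nrf2 KO replicate 1 or both replicate 1 libraries. Of 54 ribosomal protein genes, 0 passed edgeR's test, 11 were lower with the replicate block, 28 without Nrf2 KO replicate 1, 42 without both replicate 1 libraries and 0 without any 1 of the other libraries. At an unadjusted p under 0.05 edgeR gave 21 lower and 0 higher, DESeq2 called 13 lower and 0 higher, and limma-voom called 0. The median log2 fold change was -0.59, and 2 members had a positive value. The ribosomal share of counts was 6.83%, 4.62% and 5.42% in the control libraries and 4.50%, 3.31% and 3.70% in those labelled Nrf2 KO. Of 48 oxidative phosphorylation genes, 5 were lower and 0 higher (12 and 0 at an unadjusted p under 0.05, 6 and 0 by DESeq2, 5 and 0 by limma-voom, 8 and 0 with the replicate block), with a median of -0.39. Without Nrf2 KO replicate 1, 14 were lower and 2 higher, without both replicate 1 libraries 24 and 2, and without any 1 of the other libraries 0. Atp5c1, a subunit of ATP synthase, had a log2 fold change of -1.15 (SE 0.21), and Ndufs3, a complex I subunit, one of -0.91 (SE 0.17). Camera called both lists lower (adjusted p = 7.87e-08 and 8.54e-05), with an adjusted p of 0.560 each with an estimated correlation. In the paired comparison, removing a trend on transcript length from each library moved the ribosomal median from -0.59 to -0.27 and the oxidative phosphorylation median from -0.42 to -0.25. Ribosomal protein reads can be shared with pseudogenes, so single members are uncertain.

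Of 40 S phase genes, Ung, a uracil DNA glycosylase, was lower (log2 fold change -0.83, SE 0.14; 6 lower with the replicate block, 9 lower and 1 higher without Nrf2 KO replicate 1) and the median was -0.22. Of 40 G2 and M phase genes edgeR called 0 (8 higher at an unadjusted p under 0.05), DESeq2 called 5 higher, limma-voom 1 and edgeR with the replicate block 6, and their median was 0.24. Without Nrf2 KO replicate 1, 16 were higher and 0 lower, without both replicate 1 libraries 23 and 1, and without any 1 of the other libraries 0. Mki67 was at 957 ± 20.3 CPM in the control and 920 ± 37.2 CPM in the libraries labelled Nrf2 KO. Camera called the S phase list lower (adjusted p = 0.0322) and the G2 and M list higher (0.0423). With an estimated correlation the adjusted p was 0.560 and 0.646. The S phase call was lost without control replicate 2 (0.0712) or Nrf2 KO replicate 1 (0.106). The G2 and M call was kept without Nrf2 KO replicate 1 and lost without each of the other libraries (0.0508 to 0.216) and with no filter on low counts (0.0709). Ccnd1, which encodes cyclin D1, rose from 69.4 ± 9.34 to 223 ± 68.7 CPM (1.69, SE 0.28), and the inhibitor Cdkn2b rose as well (1.55, SE 0.29).

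Of 23 cholesterol synthesis genes, Stard4 (log2 fold change 0.93, SE 0.20) and Sqle (0.87, SE 0.20) were higher and 0 were lower (5 and 0 at an unadjusted p under 0.05, 4 and 0 by DESeq2 and with the replicate block, 2 and 0 by limma-voom, 10 and 0 without Nrf2 KO replicate 1). Camera called the list higher (adjusted p = 0.0322, and adjusted p = 0.585 with an estimated correlation), a call lost without control replicate 1 (0.0754) or Nrf2 KO replicate 2 (0.0789) or 3 (0.0786). Of 24 fatty acid genes, 3 were lower (Fabp5, Plin2 and Srebf1) and 1 higher (Elovl6), with 5 and 1 adjusted over the list alone and with the replicate block, and 5 and 2 without Nrf2 KO replicate 1. The list passed camera as lower without control replicate 1 (adjusted p = 0.0318) or Nrf2 KO replicate 2 (0.0202) and not with all 6 libraries (0.0621).

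**Figure D4:**
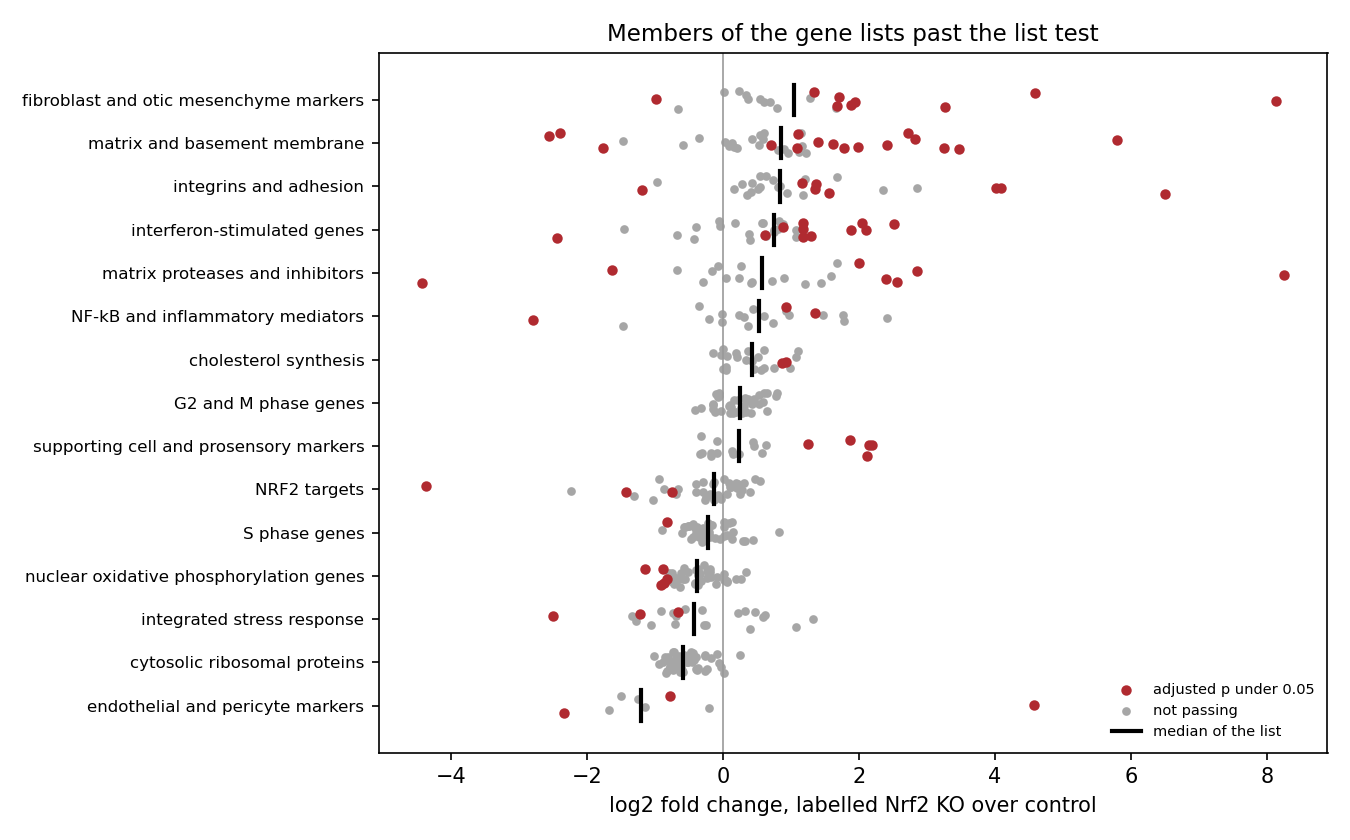
Log2 fold change, libraries labelled Nrf2 KO over control, of each tested member of the 15 lists that passed camera with a preset correlation, with members that passed the gene test in red and a black bar at the list median. List medians run from -1.20 for endothelial and pericyte markers to 1.04 for fibroblast and otic mesenchyme markers.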

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

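The fits without both replicate 1 libraries and with exact list symbols were chosen after seeing the data. Counts of called genes moved most. DESeq2 called 1420 genes higher and 1103 lower (826 and 566 at least 2-fold), with 3553 adjusted p-values not given, and kept 1209 of the 1211 calls. At an adjusted p under 0.01, 224 were higher and 109 lower (222 and 108 at least 2-fold) and 6 lists passed, and neither Nfe2l2 (log2 fold change 1.49, adjusted p = 0.0456) nor the NRF2 target list (median -0.14, adjusted p = 0.0495) did. With the replicate block 1520 were higher and 1158 lower (784 and 558 at least 2-fold), all 1211 calls were kept, and 4 lists lost their call: NRF2 targets (median -0.22, adjusted p = 0.0883), integrated stress response, NF-kB and supporting cell markers. Hsp90b1, Nqo1, Gclc and Aldh3a1 gained one, and the block changed no other call of a named gene or list. Tested against a log2 fold change of 1, 214 were higher and 88 lower. Without both replicate 1 libraries 3540 were higher and 3253 lower (988 and 790 at least 2-fold), Nfe2l2 was at 0.98, and Ctsl reversed (0.25). In that fit the median of the NRF2 target list turned positive (0.096), while camera's direction stayed lower (adjusted p = 0.853). Nfe2l2 lost its call with upper-quartile scaling (1.45, adjusted p = 0.0526) and library size alone (1.499, 0.0593). The NRF2 target list lost its call with a filter of 1 CPM (-0.13, adjusted p = 0.0632), an estimated correlation (-0.14, 0.646), under which 0 of the 15 lists passed, and exact symbols (-0.10, 0.0883), under which 12 lists passed. The NRF2 target list kept its call in 8 of 17 alternatives and Nfe2l2 in 8 of 16. Lists called only in some alternatives were immediate early genes, fatty acid metabolism, anti-apoptotic genes, ER chaperones and epithelial markers. The cause was not tested. With each library left out in turn, 139 to 2323 genes were higher and 57 to 2162 lower, 139 to 965 and 57 to 880 at least 2-fold. Nfe2l2 ranged from 1.15 to 1.71, the passing lists from 8 to 14, and the median of the NRF2 target list from -0.27 to 0.069. That median was positive without Nrf2 KO replicate 1, where camera's direction stayed lower (adjusted p = 0.845). Of uncalled genes, Ctsl ranged from -0.21 to 0.22, reversed without Nrf2 KO replicate 1, and Top2a from -0.087 to 0.55, reversed without control replicate 1 (-0.0018) or Nrf2 KO replicate 2 or 3 (-0.0092). Of 125 called genes named, median-of-ratios scaling and DESeq2 kept 125, limma-voom 124, upper-quartile and library size scaling 121 each, no filter 111 and a threshold of 0.01 kept 61, and none reversed. No scaling moved the median of all genes by more than 0.1, and the share of calls that were higher was 58.3% with TMM and 51.3% with upper-quartile scaling. Tests on FPKM were not run, as the deposited FPKM are group values. Small changes were mostly missed without the block: in a simulation with no pairing 4.04% of 2-fold changes were recovered. It used the depth and spread of these libraries together, so their parts were not tested.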

Other observations

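Signalling and stress lists outside the comparisons above held single genes that moved in both directions. Among 22 Wnt genes, the ligand Wnt6 fell from 15.7 ± 0.711 to 1.62 ± 0.299 CPM (SD, n = 3; log2 fold change -3.28, SE 0.22), while the ligand Wnt4 (1.67, SE 0.36) and the receptor Fzd1 (2.53-fold) were higher. Adjusted over the list alone 2 were higher and 2 lower, and with the replicate block 2 and 4, as against 4 and 4 without Nrf2 KO replicate 1. Of 21 epithelial-mesenchymal transition factors, 3 were higher and 2 lower (7 and 2 adjusted over the list alone, 8 and 3 with the block, 9 and 4 without Nrf2 KO replicate 1). Tgfb2, a transforming growth factor, rose from 45.7 ± 5.30 to 148 ± 23.7 CPM (1.70, SE 0.19), and Foxc2, a forkhead transcription factor, fell from 1.26 ± 0.0638 to 0.0375 ± 0.0333 CPM (-5.10, SE 0.66). Among 15 Notch genes, Notch2 was higher (0.93, SE 0.16) and Jag2, a Notch ligand, and Rfng were lower (-1.68, SE 0.34, and -0.64, SE 0.14), with the same counts over the list alone and 3 higher and 3 lower with the block, and 4 and 2 without Nrf2 KO replicate 1. Of 34 growth factor and PI3K genes, 2 were higher and 3 lower (6 and 4 over the list alone, 7 and 5 with the block, 9 and 7 without Nrf2 KO replicate 1), among them Pik3cb (0.85, SE 0.16) and Igfbp6 (-2.09, SE 0.31).

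Of 20 hypoxia targets, 3 were higher and 4 lower, over all genes and over the list alone, and 8 and 5 without Nrf2 KO replicate 1. Adm, which encodes adrenomedullin, rose from 3.16 ± 1.12 to 23.8 ± 9.85 CPM (log2 fold change 2.91, SE 0.41) and Loxl2 was higher (1.77, SE 0.25), while Ndrg1 (-1.78, SE 0.33) and Ddit4 (-1.27, SE 0.25) were lower. In the glycolysis list of 24, Pdk1, a pyruvate dehydrogenase kinase, was higher (1.10, SE 0.20) and the glucose transporter Slc2a1 lower (-0.79, SE 0.16), with 2 higher and 1 lower over the list alone 1 and 2 with the block, and 3 and 2 without Nrf2 KO replicate 1. Of 19 heat shock genes, the small chaperone Cryab was higher (2.79, SE 0.37) and Hspa1a (-1.96, SE 0.34) and Hspe1 (-0.98, SE 0.22) were lower, also over the list alone, and 2 were higher and 2 lower with the block and 3 and 3 without Nrf2 KO replicate 1. Reads of Hspa1a can be split with a near-identical copy. Of 11 Hox genes, 2 were higher, among them Hoxa4 (1.04, SE 0.20), with 0 lower by edgeR, DESeq2 and limma-voom and 1 lower at an unadjusted p under 0.05, over the list alone and with the block, and 2 higher and 3 lower without Nrf2 KO replicate 1. The oxygenase Fmo1 was lower (-2.42, SE 0.33) among 13 xenobiotic genes, with 0 higher by the 3 tools, 2 at an unadjusted p under 0.05, 2 higher and 3 lower with the block, and 3 and 3 without Nrf2 KO replicate 1. Hist1h4b, which has near-identical copies, was lower (-1.32, SE 0.19) among 7 histone genes, with 0 higher by the 3 tools and at an unadjusted p under 0.05, and 2 lower with the block.

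Of 34 autophagy and lysosome genes edgeR called 0 (3 higher and 2 lower at an unadjusted p under 0.05), DESeq2 called 2 and 2, limma-voom 0 and 1, edgeR with the block 3 and 2, and edgeR without Nrf2 KO replicate 1 10 and 2. Ctsl and Ctsb, lysosomal proteases, had log2 fold changes of -0.04 (SE 0.30) and 0.75 (SE 0.54), and without Nrf2 KO replicate 1 Ctsb was called higher (1.17, adjusted p = 0.00842). Of 24 ER chaperone genes edgeR called 0 (5 higher at an unadjusted p under 0.05), DESeq2 called 2 higher, limma-voom 1 and edgeR with the block 3. Without Nrf2 KO replicate 1, 8 were higher and 0 lower and camera called the list higher (adjusted p = 0.00597), and without both replicate 1 libraries 15 were higher and 0 lower (0.00638). Hsp90b1 was at 1060 ± 27.5 and 1692 ± 51.4 CPM (0.67, SE 0.17, adjusted p = 0.0636, and 0.0427 with the replicate block, by edgeR's quasi-likelihood test), and Hspa5 had a log2 fold change of 0.37 (SE 0.26), and 0.57 (adjusted p = 0.0192) without Nrf2 KO replicate 1. With all 6 libraries camera called none of the lists of this and the preceding 2 paragraphs. The median, the mean and camera's direction differed in sign for the antioxidant, pro-apoptotic, heat shock, glycolysis, Wnt and xenobiotic lists, and the median and mean for the leukocyte list.

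In the part that follows, the tests of exchanged labels, of scaling, of Nrf2 KO replicate 1 alone and of symbol stems were chosen only after the result was seen, and so were the fits in which the test of exchanged labels had to hold, the gene families, the bounds of the gene-order stretches and the spread required of the length test on ribosomal genes. Nfe2l2 was higher in the libraries labelled Nrf2 KO. The choice among 4 scalings is argued against, because the lowest log2 fold change over them was 1.45. They moved the median log2 fold change of all genes only between -0.013 and 0.050, so a larger error of scaling was not tested. Extra copies of its chromosome region as the whole cause cannot be decided. With all 6 libraries the 20 tested genes nearest to Nfe2l2 had a median log2 fold change of 0.424 (SE 0.118), below the bound of 0.745. That bound rests on the fold change of Nfe2l2 with all libraries, which fell as low as 1.15 with 1 library left out. The neighbours were not tested in that fit, and the SE treats neighbouring genes as independent. A smaller part stays open too, since the median is above 0. Exchanged labels, which would raise NRF2 targets, and the given labels cannot be told apart: 6 of 6 called targets were lower with the replicate block (exact binomial p = 0.03125, two-sided), but targets are co-regulated and not independent trials, and 4 were higher and 8 lower without Nrf2 KO replicate 1, and 10 and 12 without both replicate 1 libraries. A knockout that leaves the transcript in place, and a difference between cell lines unrelated to the edit, stay open and untested.

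Replicate 1 of both groups deviated from its group in the same genes, with a correlation of the deviations of 0.754 across 14618 genes (bootstrap interval 0.743 to 0.766 over genes, which are not independent replicates). Differences in depth, and transcript length as implied by the deposited tables, are argued against. The correlation was 0.764 with a trend on the implied length removed and 0.746 with the libraries thinned to 29113400 counts each. Only 77.1% of the genes had a GC value. Over these 11269 genes the correlation was 0.777 before and 0.768 after a GC trend was removed (bootstrap interval 0.755 to 0.782). That argues against GC content as the source for these genes, although both replicate 1 deviations rose weakly with GC (Spearman 0.204 in control and 0.179 in Nrf2 KO). For the genes without a GC value, GC content stays open. A shared day or batch of replicate 1, or a culture state shared by chance, stays open, since the labels do not say what the numbers mark, and no biological explanation was tested.

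Ribosomal protein and oxidative phosphorylation genes together had a median log2 difference of -0.559 over 102 genes in the paired comparison. Nrf2 KO replicate 1 as the sole cause is argued against, as the median was -0.423 (SE 0.0319 over genes) over pairs 2 and 3 alone. The medians of pairs 1, 2 and 3 were -0.83, -0.47 and -0.55 for ribosomal and -1.0, -0.28 and -0.32 for oxidative phosphorylation genes. The SEs of this paragraph treat genes as independent, although the estimated correlation between genes was 0.370 and 0.266 in the 2 lists. These SEs do not measure the spread between libraries. With a length trend removed from each library the median was -0.266 (SE 0.0386), which lies past the bound of 0.5 times the original value by less than its spread. Transcript length and an effect on these short genes cannot be told apart by that value, because the median length of ribosomal protein genes was 0.226 times that of all genes. A difference between the cell lines stays open and untested.

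Among the 10 splits of the 6 libraries into 3 and 3, the real one called 1211 genes and the highest of the others 0, so 1 of 10 splits called as many. The splits are too few for a share under 0.05. The 3 other splits that also part all 3 pairs had between 7 and 32 genes at an unadjusted p under 0.05. The split of control replicates 1 and 3 with Nrf2 KO replicate 1 had 3322, against 3654 for the real split, and 0 after adjustment.

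Fold changes ran in stretches along the mouse gene order. Over runs of 50 neighbouring genes, with the replicate block, the largest median log2 fold change in size was -0.937 (0.937 in size). It lay in a run from Fscn1 to Ubl3 with 33 genes called lower. The highest was 0.930, in a run from Acvr2a to Ccdc173 with 27 genes called higher. In 20 random orders the largest run median was at most 0.507 in size. The spread of chromosome medians exceeded that of 1000 random orders (permutation p = 0.001, the smallest they can give). Overlapping runs with a median of 0.58 or more in size were joined into stretches, of which there were 7. The largest lower one ran from Agfg2 to Rfc3 (118 genes, median -0.65), and higher ones ran from Trpv6 to Eif2ak3 (82 genes, 0.63), Asb15 to Creb3l2 (50 genes, 0.60) and Nr5a1 to Sestd1 (105 genes, 0.60), the last holding Nfe2l2. The other lower ones had medians of -0.54 (Kif3b to Srsf6), -0.51 (Hmgxb3 to Pias2) and -0.37 (Rnf14 to Slc6a7). As a hypothesis, the 2 lines may differ in copy number there, which no DNA measurement tested here. Of the 1002 called genes with a place in the order, 87.5% lay outside the stretches, against 95.1% of all placed genes. The stretches were drawn from these same fold changes, so a larger share of calls within them is built in. Nfe2l2, Gadd45a, Pdk1, Zyx and Hoxa4 lie in higher stretches and Mafk, Pms2 and Slc7a1 in lower ones, each in the direction of its fold change. Most genes of a stretch share its direction by the way it was drawn, so this match is no evidence. Against the direction of their stretch, Tmem176a and Tmem176b were lower within a higher one, and Slc12a2, not called, had a log2 fold change of 0.46 (SE 0.40) within a lower one.

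Symbols were also grouped by stem, the letters before the first digit, and every stem with at least 10 tested genes was taken as a family, so that no gene was picked. Of 292 tests, 146 stems in each of 2 directions, 4 passed Fisher's exact test with Benjamini-Hochberg adjustment, which treats the genes of a family as independent. Adamts proteases held 6 higher genes of 13 (adjusted p = 0.00233, with 2 lower) and collagens 7 of 26 (0.0170, with 1 lower), against 4.83% of all tested genes. The Akr stem of aldo-keto reductases, among which reads can be split, held 4 lower genes of 10 (adjusted p = 0.0183, with 0 higher), against 3.45%. The last test was of placeholder symbols that begin with LOC, which are no family and held fewer higher genes than the rest (53 of 2532, adjusted p = 4.75e-12). Families drawn up by hand after the largest changes were seen are given as counts with no test: 5 of 15 ephrins and Eph receptors were higher and 0 lower, 4 and 1 of 12 calcium channel subunits, and 5 and 1 of 23 integrins. Of 18 glutathione transferases 5 were lower and 0 higher: Gstt2 (log2 fold change -2.12, SE 0.15), Gsto1 (-1.32, SE 0.20), Gstp1, Gstt1 and Gstt3, and the median of all 18 was 0.0596 with TMM and -0.0103 with upper-quartile scaling. Examples of higher genes were Adamts12 (2.43, SE 0.26), Col6a3 (3.25, SE 0.42), Epha2 (1.37, SE 0.15), Cacnb2 (2.43, SE 0.30) and Itga6 (1.16, SE 0.15). These families overlap the matrix and adhesion lists described above and are not independent of them.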
